A study of Rattus norvegicus with 12 samples.

How the data were processed

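The data were 1-colour microarrays of cultured rat hepatocytes. Per the labels, livers of male and female Sprague-Dawley rats aged 11 weeks were digested by collagenase perfusion, and the cells were plated and then given dexamethasone or vehicle for 6 h before total RNA was extracted. The RNA was labelled with Cy3, per the labels, and each of the 12 samples was hybridised to its own array of a rat 4-array slide. Samples were assigned to 4 groups of 3 (male vehicle, male dexamethasone, female vehicle, female dexamethasone) from their titles, which also give a replicate number from 1 to 3. A separate sex field in the labels reads male for all 12 samples, including the 6 titled as female, so the sex used here is that of the titles. The labels do not say that replicates came from separate animals or cultures. The p-values therefore measure the spread between these samples, which may be technical.

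Each deposited array file holds, per the file headers, spot intensity values read by Agilent Feature Extraction 9.5.3.1; the submitters' processing notes name Agilent Feature Extraction 9.5. Per the file headers, the processed signal used here is an intensity on a linear scale from which Feature Extraction had subtracted the background within each array, with a small positive stand-in where a spot was not above it. No scaling between arrays had been applied to it. The authors' deposited value table of the whole series holds the same intensity values: 540216 of 540216 compared values equalled the processed signal. Its scale is therefore known to be linear and uncentred. Its column medians, over control spots too, were 44.7, 47.1 and 63.6 for male vehicle replicates 1 to 3, and 80.6, 95.5 and 98.1 for male dexamethasone. They were 109, 80.6 and 112 for female vehicle and 103, 103 and 99.1 for female dexamethasone.

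Each array file holds 43379 spots that are not controls, from 41012 probes. Spots that Feature Extraction marked as outliers were left out, saturated spots were kept, and spots of 1 probe were averaged as log2 values. The main setting was the log2 processed signal minus each array's 75th percentile of it. Probes were kept where they were well above background on all 3 arrays of at least 1 group, which left 30978 probes. Gene names came from the file, updated through a table of RefSeq genes by accession, symbol or older symbol. That table named 19926 probes, 21086 kept the name in the file, and 157 names were refused because the table placed the gene on another chromosome. A gene with several kept probes (3610 genes) was represented by the probe with the highest mean signal over all 12 arrays. This gave 26535 genes, of which 12595 carry a gene symbol. Positions of probes are those of the files, on rat genome build rn3, per the file headers. What lies at a position is given by gene name alone, since no annotation of that build was used here.

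Groups were compared with limma 3.58.1 in R 4.3.3. One model with 4 group means was fitted to all 12 arrays, so that the groups share an estimate of the spread, followed by lmFit, contrasts.fit and eBayes with Benjamini-Hochberg adjustment. Where a group varies more than the others, the shared estimate understates its own spread. All tests were two-sided and the threshold was an adjusted p of 0.05. The dexamethasone response was tested in each sex, the difference between these responses was tested as an interaction, and females were compared with males in vehicle and in dexamethasone. Signed differences are dexamethasone minus vehicle, or female minus male. Errors given as ± after a log2 difference are standard errors of the fit, and those after a level are SDs over 3 arrays. Arrays give no read depth, and the number of arrays limits the precision.

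Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 27 lists that had at least 5 measured members out of 28 written. The estimated correlation and fry were alternatives. The lists, the samples, the design and most alternatives were fixed before the data were examined, as was the rule for named genes. That rule takes the 8 largest rises and the 8 largest falls among genes past the threshold whose arrays do not overlap between groups (5 each for the sexes in dexamethasone). It adds up to 2 rises and 2 falls from each list that pass, or the member with the smallest p where none does, and a set of sentinel genes given in every comparison. Where a gene was not well above background on any array of a group, its fold change is a bound, written "at least N-fold". The bound sets the brighter group's mean against the mean, over the dim group's arrays, of the higher of the lowest signal among probes well above background and the probe's own signal. No fold is given where both groups were below background.

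Array positions show 3 slides of 4 arrays. Slide 1 held the 3 male vehicle arrays and male dexamethasone replicate 1; slide 2 held male dexamethasone replicates 2 and 3 with female vehicle replicates 1 and 2; slide 3 held female vehicle replicate 3 with the 3 female dexamethasone arrays. Each comparison was therefore also fitted with slide as a block. By the layout, the slide-blocked male response equals the difference within slide 1, and the slide-blocked female response that within slide 3, for gene lists too. The blocked fits reuse arrays by which genes were called without a block. A kept sign or a similar size in them is therefore no independent check. No slide held both sexes in 1 treatment, so the blocked sex differences rest on the chain of slides. Whether replicate numbers pair samples was checked across genes by the correlation of deviations from group means. Vehicle and dexamethasone arrays of the same number and sex correlated at 0.352 to 0.599 in all 6 pairs, and other pairs within a sex at -0.419 to -0.0525. The numbers were taken to pair samples within a sex, and a fit with these pairs as blocks was an alternative. Across sexes only the number is shared and pairing was not checked; a fit with the number as a block was run there too, as an alternative.

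The other alternatives were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization of the processed signal, each array's median as the scale, and the authors' value table. The filter was dropped, or tightened to probes above background on all 12 arrays, and slide was also used as a random block and as single slides. Other fits used only the arrays of the groups compared, the mean of a gene's probes or the probes singly, eBayes with trend and robust options, array weights, stricter thresholds, and each array left out in turn. Those added after the data were seen were slide and replicate blocks together, a common floor for dim signals at -3.37, genes above background on all arrays compared, and the fit without slide 1. The fits were tested on simulated data with known changes over 26322 genes. No slide effect and no shared deviation of replicate pairs were simulated. Each gene had the same spread on all arrays, unlike the real groups, and only 66 or 67 genes were changed per size of change. The shares recovered are therefore not the power in the real data. For a log2 change of 2 the unblocked fit recovered 80.3% of changed genes in the male response, 78.8% in the female response, 56.1% in the interaction, 72.7% between the sexes in vehicle and 78.8% in dexamethasone. For a log2 change of 1 it recovered 17.9%, 23.9%, 5.97%, 11.9% and 31.3%. With slide as a block and a log2 change of 2, it recovered 39.4%, 36.4%, 0%, 0% and 0%. With replicate pairs as blocks, or between the sexes the replicate number alone, it recovered 65.2%, 62.1%, 0%, 69.7% and 66.7%.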

Results

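RNA was measured in primary hepatocytes, the metabolic cells of the liver, of Sprague-Dawley rats of both sexes. The cultures had been exposed for 6 h to dexamethasone, a synthetic glucocorticoid, at 100 nM (the labels write "nm") or to its 0.01% ethanol vehicle. The 12 samples formed 4 groups of 3 (male vehicle, male dexamethasone, female vehicle, female dexamethasone), each hybridised to its own 1-colour Agilent array. The series asks, by its title, how a glucocorticoid changes expression across the genome in hepatocytes of each sex. The design gives 5 comparisons: the response in males, the response in females, the difference between these responses, and females against males in vehicle and in dexamethasone.

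The arrays differed in quality by slide. The share of probes well above background was 46.0%, 46.8% and 55.7% on male vehicle replicates 1 to 3 and 66.5% on male dexamethasone replicate 1, the 4 arrays of slide 1, against 72.4% to 80.4% on the other 8. The median coefficient of variation of replicate probes within an array was 14.1% to 21.1% on slide 1 and 4.59% to 8.47% elsewhere. The 75th percentile of the processed signal ran from 509 to 1241 over the 12 arrays. Replicates correlated across genes at 0.964 or above, with a median SD between arrays of 0.31 log2 units in male vehicle, 0.21 in male dexamethasone, 0.15 in female vehicle and 0.13 in female dexamethasone. A gene had to be brighter to be measured in male vehicle than elsewhere: 887 of the genes called in the male response were above background on none of the 3 male vehicle arrays. In a principal component analysis of 14733 genes, the first component took 31.6% of the variance and separated the sexes, and the second took 24.9% and separated dexamethasone from vehicle.

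**Figure D1:**
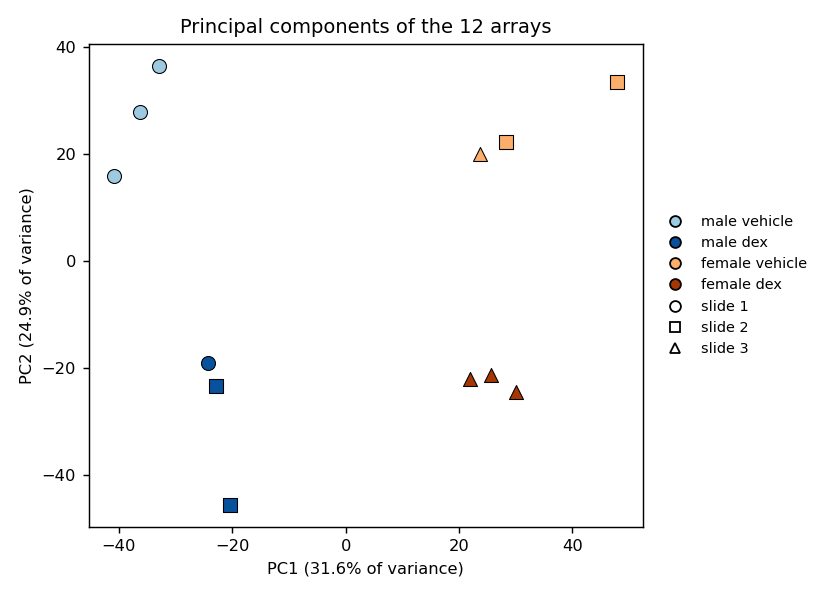
Principal components 1 (31.6% of variance, x axis) and 2 (24.9%, y axis) of 14733 genes, with 1 point per array, colour for the group and marker shape for the slide. Male arrays lie at negative and female arrays at positive values of component 1; the vehicle arrays lie above 0 and the dexamethasone arrays below 0 on component 2.

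The titled sex was checked against genes known to differ between male and female rats. A single probe, on rn3 chromosome X at 91523230 to 91523289, is described in the files as similar to Xist, the transcript of the inactive X chromosome. It was found by its description after the other values had been seen. It was at 0.46 to 1.16 log2 units relative to the array's 75th percentile on the 6 arrays titled female and at -6.76 to -5.30 on the 6 titled male, where 2 arrays, of male dexamethasone, were above background. No probe was named or described as Ddx3y. Obp3, an odorant-binding protein of the lipocalin family secreted by male rat liver, was at 2.93 to 4.26 on each of the 6 arrays titled male. It was not above background on any of the 6 titled female. The female-specific Cyp2c12 was higher on every array titled female (3.79 to 4.82) than on any titled male (0.86 to 2.77). No sample was regrouped.

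In male hepatocyte cultures, dexamethasone raised several classical glucocorticoid targets and several enzymes of amino acid breakdown and glucose production. It lowered several chemokine genes and interleukin 1 genes. Kupffer cell markers were measured too, 14 of 15 above background on all male vehicle arrays. Which cells of the cultures, of either sex, these changes came from was not tested. Fkbp5, a co-chaperone that limits glucocorticoid receptor signalling, rose from 0.91 ± 0.11 to 3.84 ± 0.36 log2 units (SD, n = 3 each), 7.60-fold (difference 2.93 ± 0.18, adjusted p = 4.5e-05). Tat, tyrosine aminotransferase, rose 7.08-fold from 1.52 ± 0.08 to 4.34 ± 0.37 (2.82 ± 0.21, adjusted p = 0.0001), and Tdo2, which opens the tryptophan ring, rose 15.4-fold (3.94 ± 0.42, adjusted p = 0.00082). Il1b, the interleukin 1 beta gene, fell from 0.94 ± 0.19 in 2 male vehicle arrays, since its spot was marked as an outlier on replicate 2, to -3.93 ± 0.75 (difference -4.87 ± 0.39, adjusted p = 0.0003). The monocyte chemokine Ccl7 was 12.1-fold lower (SE 0.23 log2 units, adjusted p = 4.5e-05). On rn3 the probes of Fkbp5 lie at chromosome 20, 6637827 to 6637886, of Tat at chromosome 19, 39868729 to 39868788, of Il1b at chromosome 3, 116870289 to 116870348, and of Ccl7 at chromosome 10, 70282297 to 70282356.

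**Figure D2:**
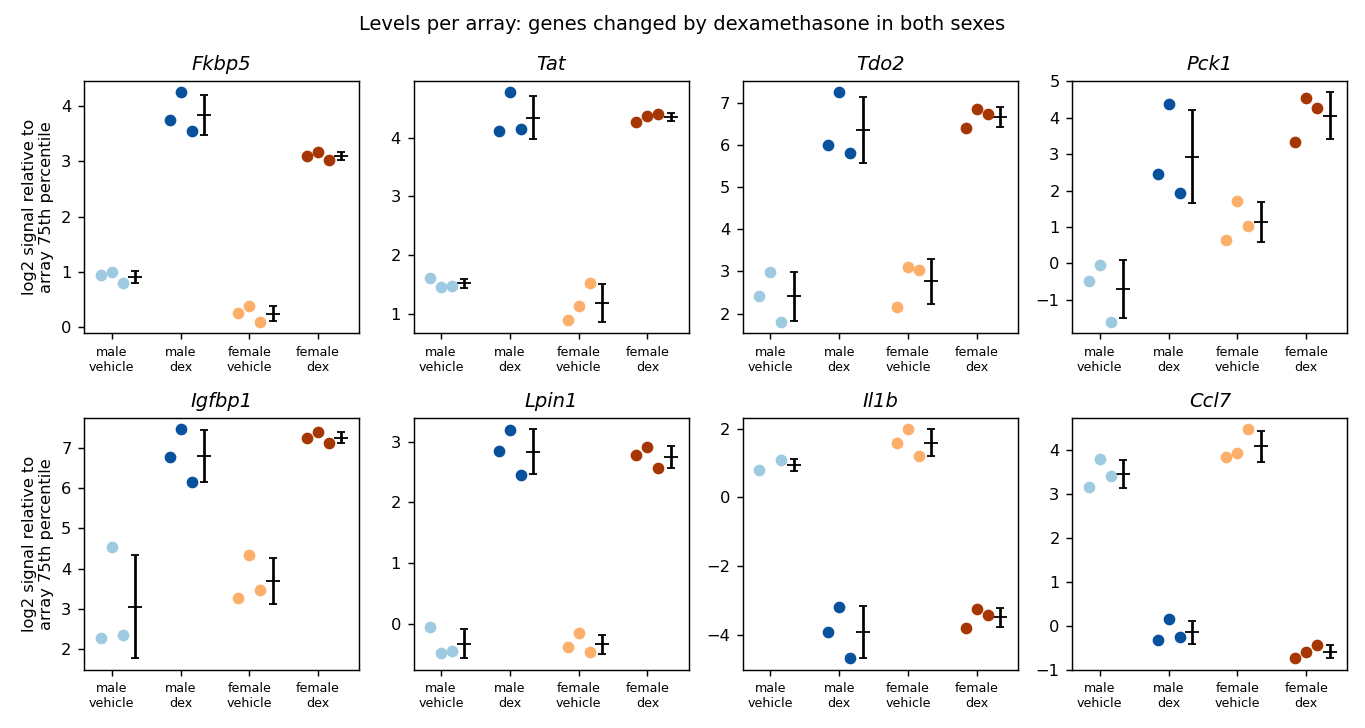
Log2 signal relative to each array's 75th percentile (y axis) for 8 genes in the 4 groups (x axis), with 1 point per array, filled where the probe was well above background and open where it was not, and bars for the mean ± SD. Fkbp5 and Tat rise with dexamethasone in both sexes, to 3.84 and 4.34 in males and 3.09 and 4.35 in females, and Il1b falls to -3.93 and -3.50.

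Of the 29 measured genes of the textbook list of glucocorticoid-induced genes, 15 rose and 0 fell in males (18 and 0 adjusted over the list alone), with a list median of 1.06 (camera adjusted p = 5.6e-14; adjusted p = 0.000507 with an estimated correlation). In the slide-blocked fit 4 of them passed, and the median was 0.98 (camera adjusted p = 2.4e-12, and 0.0044 in that fit with an estimated correlation). Besides Fkbp5, the transcription factor Zbtb16 rose (adjusted p = 4.5e-05). It was not above background on any male vehicle array and was at least 6.12-fold higher with dexamethasone. The anti-inflammatory leucine zipper Tsc22d3 rose by 1.31 ± 0.21 (adjusted p = 0.0055) and the clock gene Per1 by 1.25 ± 0.26 (adjusted p = 0.015). The phosphatase Dusp1 (0.86 ± 0.36, adjusted p = 0.16) and the glucocorticoid receptor gene Nr3c1 (0.67 ± 0.29, adjusted p = 0.17) did not pass; with replicate pairs as blocks Nr3c1 did (adjusted p = 0.029).

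Of the 37 inflammation, chemokine and cytokine genes measured, 20 fell and 0 rose in males (20 and 1 adjusted over the list alone), with a median of -1.22 (camera adjusted p = 1.5e-08; adjusted p = 0.311 with an estimated correlation). In the slide-blocked fit 5 fell, at a median of -1.15 (camera adjusted p = 4.8e-09, and 0.563 in that fit with an estimated correlation). The membrane-bound chemokine Cx3cl1 was 16.0-fold lower (adjusted p = 0.0014), and the chemokine Ccl12 differed by -4.28 ± 0.51 (adjusted p = 0.0014). Il1a differed by -3.51 ± 0.39 (adjusted p = 0.001) and Cxcl6 by -3.89 ± 0.76 (adjusted p = 0.012); Il1a was above background on 2 of 3 arrays of each male group, Cxcl6 on 2 and 1. Il1r2, the decoy receptor that binds interleukin 1, rose by 5.04 ± 0.49 (adjusted p = 0.00059) from a level that 1 of 3 male vehicle arrays measured.

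Of 27 genes of gluconeogenesis and amino acid breakdown, 9 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 1.2e-05; adjusted p = 0.746 with an estimated correlation). Slide as a block left 2 rises, at a median of 0.26 (camera adjusted p = 0.00172, and 0.984 in that fit with an estimated correlation). Pck1, which commits carbon to glucose production, rose 12.4-fold (3.63 ± 0.62, adjusted p = 0.0067). Igfbp1, a binding protein of insulin-like growth factors, rose 13.4-fold (3.75 ± 0.56, adjusted p = 0.0035).

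Other large rises in males included single genes of several functions. The phosphatidate phosphatase Lpin1 rose 8.97-fold (3.16 ± 0.21, adjusted p = 4.5e-05). The mitochondrial carrier Slc25a47 rose by 4.19 ± 0.57 (adjusted p = 0.0025) and the aldo-keto reductase Akr1c14 by 3.51 ± 0.32 (adjusted p = 0.00035). Ppara, the receptor that drives fatty acid oxidation, rose by 2.28 ± 0.23 (adjusted p = 0.00067), and the insulin receptor substrate Irs2 by 1.40 ± 0.19 (adjusted p = 0.0024). Tent5b, not above background on any male vehicle array, was at least 6.69-fold higher (adjusted p = 0.003). The citrate carrier Slc13a5 (4.52 ± 0.96, adjusted p = 0.017) and the retinol dehydrogenase Rdh16 (4.24 ± 0.60, adjusted p = 0.0029) rose from levels that 2 of 3 male vehicle arrays measured. The protease inhibitor A2m rose by 5.41 ± 1.20 (adjusted p = 0.021), with an SD of 2.82 between male vehicle arrays. Akr1b10 and Tfpi2, among the largest calculated falls, were above background on no array of either male group, so no fold is given.

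The other lists did not pass in males, and members of several went both ways. Of 25 fatty acid oxidation genes, 5 rose and 1 fell (Fgf21, -1.38 ± 0.32, adjusted p = 0.025), with camera adjusted p = 0.0916. The Fgf21 call was lost without male vehicle replicate 2 or 3 or male dexamethasone replicate 1 or 2 (adjusted p up to 0.0841). Of 20 female-biased liver genes 3 rose and 3 fell, and of 22 apoptosis genes 3 rose and 4 fell. The interferon-induced Rsad2 fell by 2.52 log2 units (SE 0.52, adjusted p = 0.015), and 4 of 29 interferon-response genes fell and 0 rose. No list of markers of other liver cell types passed in males. Of 11 cholangiocyte markers 2 rose, among them Cldn4 (0.95 ± 0.17, adjusted p = 0.0093), and 0 fell (3 and 1 adjusted over the list alone; 4 and 1 with replicate pairs as blocks), with a median of -0.19 (camera adjusted p = 0.326). The Cldn4 call was lost with slide as a block (adjusted p = 0.0505). In males 0 of 15 Kupffer cell and 0 of 10 lymphocyte markers passed. Of 12 stellate-cell and fibroblast markers 0 rose and 1 fell, Hgf, and of 12 endothelial markers 1 rose, Lyve1, and 1 fell, Emcn. Hgf and Emcn were above background on no array of either group. Lyve1 (3.41 ± 0.78, adjusted p = 0.023) was above background on 1 male vehicle array and lost its call without male vehicle replicate 2 or any male dexamethasone array (adjusted p up to 0.0725). The stellate list had a median of 0.07 in males. The male-specific Cyp2c11 (-0.51 ± 0.67, adjusted p = 0.68) did not pass, though it did with replicate pairs as blocks (adjusted p = 0.036), and Cyp2c12 did not (-0.30 ± 0.44, adjusted p = 0.72).

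In the limma fit over 26535 genes, 2676 passed in males, 1382 higher and 1294 lower with dexamethasone (7154 at an unadjusted p under 0.05). This fit shares the spread between groups, while the median SD between arrays was 0.31 in male vehicle and 0.13 in female dexamethasone. Its errors and p-values may therefore understate the spread of male vehicle. A fit to only the male groups called far fewer genes, as given with the female counts. The arrays of the groups did not overlap for 25.7% of genes, against 10% if all 6 arrays were exchangeable. Slides, array quality and replicate pairs break that condition, so this excess, here and below, does not by itself show an effect of the groups. Above background on all 6 arrays were 569 of the rises and 898 of the falls. A total of 887 calls were above background on no male vehicle array: 549 rises, and falls whose starting level was not measured. Of these falls, 124 were above background on no array of either group, so they have no measured level. The share of higher calls was 51.6% with the 75th percentile, 66.8% with quantile normalization (2276 higher, 1129 lower) and 31.9% with the array median (1016 and 2166). The median difference of all genes was -0.07, 0.04 and -0.19 in these settings, so a change near these values has no settled direction, while the camera tests compare each list with the other genes. With slide as a block 471 genes passed, 188 higher and 283 lower, and 311 of them were called the same way without it. Within slide 1 alone, where male dexamethasone is 1 array, limma called 0 genes (2105 at an unadjusted p under 0.05). With replicate pairs as blocks 4175 passed, 1910 higher and 2265 lower. All 2676 genes kept their sign in the slide-blocked fit, in which the blocked difference was a median 0.962 of the unblocked one and the standard error 1.41 times as large. This is no independent check, since the blocked difference comes from arrays by which these genes were called. The blocked differences were 2.83 for Fkbp5, 2.59 for Tat, -4.85 for Il1b and -3.78 for Ccl7 (adjusted p 0.0043 to 0.017), and Zbtb16 passed too (adjusted p = 0.0091). They were 3.17 for Pck1 (adjusted p = 0.13), 3.71 for Igfbp1 (adjusted p = 0.072), 1.27 for Tsc22d3 (adjusted p = 0.095), 1.37 for Per1 (adjusted p = 0.12) and 6.03 for A2m (adjusted p = 0.14). Of 64 named genes that passed, 40 kept their call whichever array was left out. The call of A2m was lost without male dexamethasone replicate 1 or 2 (adjusted p up to 0.0757) and that of Per1 without male dexamethasone replicate 3 (adjusted p = 0.0542). The count was 1173 without male dexamethasone replicate 2 and 1417 without replicate 3.

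In female hepatocyte cultures the glucocorticoid targets Fkbp5, Tat and Tdo2 rose, and Il1b and Ccl7 fell, as in males. Fkbp5 rose from 0.25 ± 0.14 to 3.09 ± 0.07 log2 units (SD, n = 3 each), 7.18-fold (2.84 ± 0.18, adjusted p = 4.7e-05), and Tat from 1.18 ± 0.32 to 4.35 ± 0.07, 8.95-fold (3.16 ± 0.21, adjusted p = 5.1e-05). Tdo2 rose 14.9-fold (3.90 ± 0.42, adjusted p = 0.00086). Il1b fell from 1.59 ± 0.39 to -3.50 ± 0.28 (difference -5.09 ± 0.35, adjusted p = 0.00011) and Ccl7 fell by 4.67 (SE 0.23, adjusted p = 6.1e-06).

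Of the 29 glucocorticoid-induced genes, 13 rose and 0 fell in females (19 and 1 adjusted over the list alone), with a median of 1.11 (camera adjusted p = 7.4e-17; adjusted p = 0.000252 with an estimated correlation). Slide as a block left 6 rises, at a median of 0.97 (camera adjusted p = 7.6e-13, and 0.00392 in that fit with an estimated correlation). Zbtb16 rose by 4.32 ± 0.30 (adjusted p = 5.6e-05), the sulfotransferase Sult1a1 13.7-fold (3.78 ± 0.47, adjusted p = 0.0021) and Tsc22d3 3.89-fold (1.96 ± 0.21, adjusted p = 0.00095). Per1 rose by 1.28 ± 0.26 (adjusted p = 0.022). Dusp1 (1.29 ± 0.36, adjusted p = 0.075) and Nr3c1 (0.27 ± 0.29, adjusted p = 0.76) did not pass.

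Of 37 inflammation genes, 14 fell and 0 rose (21 and 0 adjusted over the list alone), with a median of -0.87 (camera adjusted p = 6.7e-15; adjusted p = 0.0779 with an estimated correlation). Slide as a block left 5 falls, at the same median (camera adjusted p = 2.3e-11, and 0.367 in that fit with an estimated correlation). The monocyte chemokine Ccl2 fell by 3.31 log2 units (SE 0.25, adjusted p = 8.4e-05), Ccl12 by 3.46 (SE 0.51, adjusted p = 0.0051) and Il1a by 3.31 (SE 0.39, adjusted p = 0.0015). Ptgs2, the inducible cyclooxygenase, fell below background with dexamethasone and was at least 6.07-fold lower (adjusted p = 0.00022), and the hyaluronan synthase Has2 was at least 5.24-fold lower (adjusted p = 0.00049). Of 27 gluconeogenesis and amino acid genes, 9 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.68 (camera adjusted p = 1.3e-09; adjusted p = 0.299 with an estimated correlation). Slide as a block left 2 rises, at a median of 0.56 (camera adjusted p = 4.9e-07, and 0.656 in that fit with an estimated correlation). Pck1 rose 7.60-fold (2.93 ± 0.62, adjusted p = 0.027) and Igfbp1 11.8-fold (3.56 ± 0.56, adjusted p = 0.0071).

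Other large rises in females included Tekt5l1 (at least 11.2-fold, adjusted p = 0.00039) and Chrdl1, an antagonist of bone morphogenetic proteins (at least 11.0-fold, adjusted p = 0.00069); neither was above background on a female vehicle array. Tent5b rose by 5.07 ± 0.62 (adjusted p = 0.0017), above background on 2 of 3 female vehicle arrays, and Slc25a47 by 4.50 ± 0.57 (adjusted p = 0.0023). The glucuronosyltransferase Ugt2a3 (3.92 ± 0.54, adjusted p = 0.0037) and AKR1C3l1 (3.91 ± 0.44, adjusted p = 0.0011) rose from levels that 1 female vehicle array measured. Lpin1 rose 8.50-fold (3.09 ± 0.21, adjusted p = 5.5e-05) and Ppara 5.14-fold (2.36 ± 0.23, adjusted p = 0.00049). Cyp27a1, a sterol hydroxylase of bile acid synthesis, rose by 1.60 ± 0.25 (adjusted p = 0.0078), and Hamp, which encodes the iron hormone hepcidin, by 1.57 ± 0.19 (adjusted p = 0.0014). Cyp2c11 (0.05 ± 0.67, adjusted p = 0.99) and Cyp2c12 (-0.57 ± 0.44, adjusted p = 0.62) did not pass.

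In females 10 further lists passed camera, none of them with an estimated correlation. Stellate-cell and fibroblast markers had a median of -0.75 (camera adjusted p = 0.000431; adjusted p = 0.193 with an estimated correlation). Of 12 such markers 1 fell, the receptor Pdgfrb (-1.13 ± 0.28, adjusted p = 0.046), 2 fell adjusted over the list alone, and with slide as a block the median was -0.33 (adjusted p = 0.106). The Pdgfrb call was lost with replicate pairs as blocks (adjusted p = 0.058). The cell cycle list had a median of -0.27 (camera adjusted p = 0.0147; adjusted p = 0.474 with an estimated correlation) with 0 of 28 members past the threshold, and a slide-blocked adjusted p of 0.581. Medians above 0 were found for hepatocyte identity (0.23, adjusted p = 0.0126), acute phase (0.19, adjusted p = 0.0147), fatty acid oxidation (0.25, adjusted p = 0.0195) and male-biased liver genes (0.25, adjusted p = 0.0195), and these passed with slide as a block (adjusted p 0.0213 to 0.045). With an estimated correlation their adjusted p ran from 0.464 to 0.586, and from 0.728 to 0.767 with slide as a block as well. Among their members, the urea cycle enzyme Cps1 rose 5.67-fold (adjusted p = 0.035) and Hsd11b1, which regenerates active glucocorticoid, by 1.53 ± 0.26 (adjusted p = 0.01). Nuclear receptors (0.19, adjusted p = 0.0271) and xenobiotic metabolism (0.32, adjusted p = 0.0271) did not pass with slide as a block (adjusted p = 0.0772 and 0.106), nor with an estimated correlation (adjusted p = 0.464 and 0.586). The insulin and growth hormone list (0.06, adjusted p = 0.0474) and the heat shock list (-0.15, adjusted p = 0.0482) did not pass with replicate pairs as blocks (adjusted p = 0.0513 and 0.0543) or with an estimated correlation (adjusted p = 0.414 and 0.464). In females 0 of 15 Kupffer cell and 0 of 10 lymphocyte markers passed, and 1 of 12 endothelial markers rose, Vwf (1.75 ± 0.40, adjusted p = 0.036). With replicate pairs as blocks 2 lists passed that did not without them: bile acid genes (median 0.39, adjusted p = 0.00554) and cholangiocyte markers (-0.50, adjusted p = 0.0264). Neither passed in that fit with an estimated correlation (adjusted p = 0.185 and 0.253).

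In the limma fit 1098 of 26534 genes passed in females, 799 higher and 299 lower with dexamethasone (4573 at an unadjusted p under 0.05). The groups did not overlap for 33.8% of genes, against 10% for exchangeable arrays, and 57 rises started below background. The share of higher calls was 72.8%, and 61.9% with the array median as the scale (576 and 354). In the slide-blocked fit 300 passed, 215 higher and 85 lower, of which 224 were called the same way without it. All 1098 genes kept their sign, in arrays by which they were called. Within slide 3 alone, with 1 female vehicle array, 1371 passed. With replicate pairs as blocks 1793 passed, 1136 higher and 657 lower, and without the 4 arrays of slide 1 the count was 2417. Which sex has more calls depends on how the spread is estimated: fits to only the 2 groups compared called 2675 genes in females and 244 in males. The slide-blocked differences were 2.99 for Fkbp5, 2.82 for Tat, 4.29 for Zbtb16, 2.01 for Tsc22d3, -4.71 for Il1b and -5.06 for Ccl7 (adjusted p 0.0011 to 0.038), 3.03 for Pck1 (adjusted p = 0.18), 3.79 for Igfbp1 (adjusted p = 0.081) and 1.26 for Per1 (adjusted p = 0.19). Of 49 named genes that passed, 30 kept their call whichever array was left out. Pck1 lost it without female vehicle replicate 1 or 3 or any female dexamethasone array (adjusted p up to 0.109), Per1 without any 1 of the 6 female arrays (up to 0.099), and Hsd11b1 without female dexamethasone replicate 2 (0.0533). Pdgfrb lost it without any 1 of the 6 female or 3 male dexamethasone arrays (up to 0.178), Vwf without any 1 of the 6 female arrays or male dexamethasone replicate 3 (up to 0.139), and Cps1 without female vehicle replicate 1 or 3, male dexamethasone replicate 3 or female dexamethasone replicate 2 or 3 (up to 0.132). The count was 357 without female vehicle replicate 1, 349 without replicate 3, and 312, 310 and 382 without female dexamethasone replicates 1, 2 and 3.

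The responses of the sexes overlapped. Of the 1382 genes higher in males and 799 higher in females, 367 were shared, against 41.6 for independent lists of these sizes, and of the 1294 and 299 lower genes 162 were shared, against 14.6. A further 17 genes were called in opposite directions. The shared calls were 48.2% of the female and 19.8% of the male calls. Of the 2130 genes called in males and not in females, 78.2% had the same sign in females, and of the 552 called in females and not in males, 67.0% had the same sign in males. Across all genes kept by the filter on dim probes, which are not independent replicates, the log2 responses correlated at 0.51 (Pearson) and 0.41 (Spearman), and at 0.66 and 0.63 over the 3228 genes called in either sex. Pearson's r over all genes was 0.116 without that filter, 0.655 with probes above background on all 12 arrays and 0.368 with slide as a block. The responses share no arrays. Under the slide block 90 genes were shared in direction, 59 higher and 31 lower, against 1.52 and 0.907, and with replicate pairs as blocks 1015. The shared number was 212 without female dexamethasone replicate 1, 210 without replicate 2, 250 without replicate 3, and 222 and 225 without female vehicle replicates 1 and 3.

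**Figure D3:**
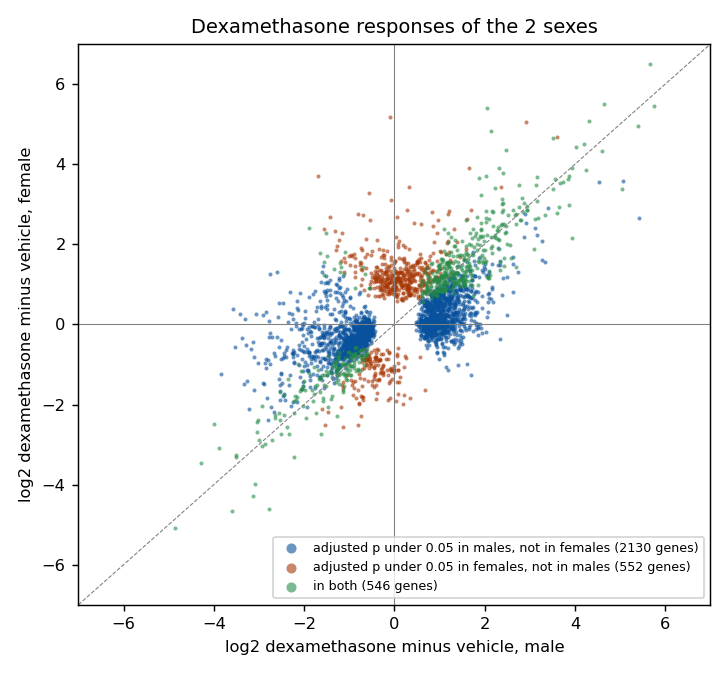
Log2 dexamethasone response in males (x axis) against that in females (y axis) for genes with an adjusted p under 0.05 in males and not females (2130), in females and not males (552) or in both, with 1 point per gene and a dashed line at equal responses. Of the genes called in both, 529 lie in the same direction in both sexes and 17 in opposite directions.

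Among the sentinel genes of the response, none differed between the sexes by the interaction test. The female minus male difference of the response was -0.08 ± 0.26 for Fkbp5 (adjusted p = 0.95), 0.34 ± 0.30 for Tat (0.74), 0.64 ± 0.30 for Tsc22d3 (0.43), 0.03 ± 0.36 for Per1 (0.99), -0.71 ± 0.87 for Pck1 (0.83), -0.18 ± 0.79 for Igfbp1 (0.97) and 0.43 ± 0.51 for Dusp1 (0.82). Genes whose response did differ included Reg3a, a secreted C-type lectin, with a difference of 2.13 ± 0.23 (adjusted p = 0.027), and the zinc finger gene Zfp474 with 1.92 ± 0.21 (adjusted p = 0.027). Over 26534 genes 28 passed, 20 with a higher and 8 with a lower response in females (3208 at an unadjusted p under 0.05), and 18 of the 28 were above background on none of the 3 male vehicle arrays. The share of higher differences was 71.4%, and 12.3% with quantile normalization (36 higher, 257 lower); the median difference of all genes was 0.07, -0.05 with quantile normalization and 0.12 with the array median. Under the slide block 2 genes passed, 2 higher and 0 lower, and none of the 28 did. With replicate pairs as blocks limma called 0 (4382 at an unadjusted p under 0.05). In simulated data each of these blocked fits recovered 0% of interaction genes with a log2 change of 2. The simulation held no slide effect, no shared deviation of replicate pairs and no larger change, so it cannot say what the lost calls mean. With slide as a block the differences of the 28 genes were a median 1.012 of the unblocked ones, in a fit to the same arrays. The count was 0 without any 1 of the female dexamethasone arrays or female vehicle replicate 1 or 3, 10, 9 and 3 without male dexamethasone replicates 1, 2 and 3, 113 without female vehicle replicate 2, and 108 and 579 without male vehicle replicates 1 and 3. The calls of Reg3a and Zfp474 were lost without female vehicle replicate 1 or 3, male dexamethasone replicate 3 or any female dexamethasone array (adjusted p up to 0.103).

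In vehicle, female and male hepatocytes differed in many, not all, of the genes known to be sex-biased in rat liver. Obp3 was at least 1543-fold lower in females (adjusted p = 2.8e-08, n = 3 per group), and the major urinary protein gene Mup4 at least 10.38 log2 units lower (adjusted p = 4.3e-07). Other probes of the same family, named Mup5, Mup4l1, Mup4l3 and Mup4l4, differed by -10.78 to -13.60; each was above background on 2 or 3 of the 3 female vehicle arrays. Their sequences are near-identical, so which member was measured is uncertain. Cyp2c12 was 6.19-fold higher in females (4.55 ± 0.35 against 1.92 ± 0.77; SD, difference 2.63 ± 0.44, adjusted p = 0.0048). Cyp2c7, another cytochrome P450 of female liver, was higher by 6.15 ± 0.59 (adjusted p = 0.00041) over a male level that 1 array measured. The male-specific Cyp2c11 was 4.99-fold lower in females (-2.32 ± 0.67, adjusted p = 0.044) and Cyp3a2 26.1-fold lower (-4.71 ± 1.22, adjusted p = 0.03). The probe of Obp3 lies on rn3 chromosome 5, 78095776 to 78095835, and that of Pdgfrb on chromosome 18, 57125637 to 57125695.

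**Figure D4:**
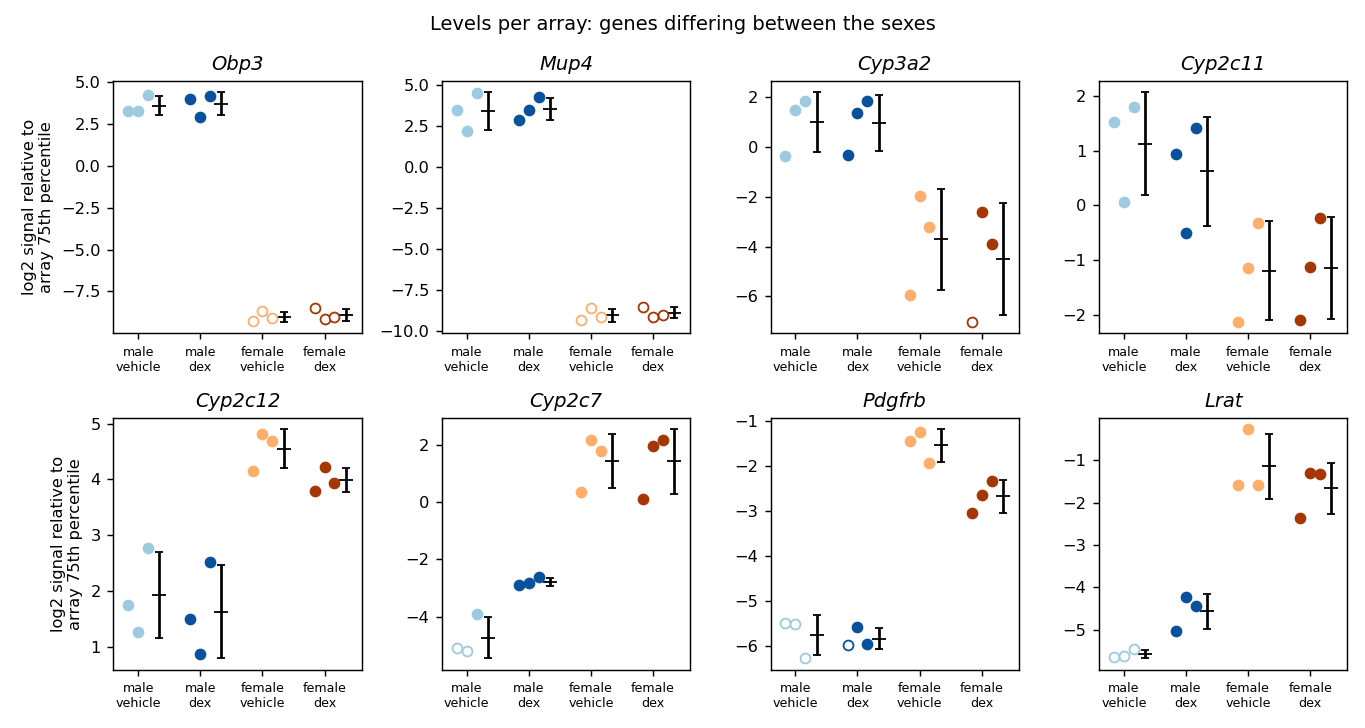
Log2 signal relative to each array's 75th percentile (y axis) for 8 genes in the 4 groups (x axis), with 1 point per array, filled where the probe was well above background and open where it was not, and bars for the mean ± SD. Obp3 and Mup4 lie below background on all 6 female arrays, and Cyp2c12, Cyp2c7, Pdgfrb and Lrat lie higher on every female than on any male array.

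Of 20 female-biased liver genes, 13 were higher and 1 lower in females (13 and 1 adjusted over the list alone), with a median of 1.00 (camera adjusted p = 3.5e-06; adjusted p = 0.0823 with an estimated correlation; 1.18 and adjusted p = 8.5e-05 with slide as a block). The sulfotransferases Sult2a2 (at least 11.3-fold, adjusted p = 0.0026) and Sult2a6 (5.65 ± 0.91, adjusted p = 0.0043) and the aldo-keto reductase Akr1b7 (at least 9.86-fold, adjusted p = 0.0013) were higher in females. Sult2a probes, like those of the Akr1c and Mup families, name close paralogs, so which member was measured is uncertain. The testosterone-reducing enzyme Srd5a1 was higher by 1.24 ± 0.17 (adjusted p = 0.0022). The member that went against the list was Slc22a8, an organic anion transporter, lower in females by -4.18 ± 0.50 (adjusted p = 0.0012). Of 16 male-biased genes, 9 were lower and 0 higher (11 and 1 adjusted over the list alone), with a median of -2.08 (camera adjusted p = 1.2e-04; adjusted p = 0.332 with an estimated correlation; -1.90 and adjusted p = 2.7e-06 with slide as a block). With slide as a block and an estimated correlation neither sex-biased list passed (camera adjusted p = 0.21 each). Hsd11b1 was lower by -1.85 ± 0.26 (adjusted p = 0.0022). The glucocorticoid targets Tsc22d3 (-1.01 ± 0.21, adjusted p = 0.013) and Fkbp5 (-0.66 ± 0.18, adjusted p = 0.038) were lower in female vehicle cultures, while Tat (-0.34 ± 0.21, adjusted p = 0.31), Nr3c1 (0.58 ± 0.29, adjusted p = 0.21) and Per1 (-0.33 ± 0.26, adjusted p = 0.43) did not pass.

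Markers of some other liver cells were also higher in the female vehicle cultures. Of 12 stellate-cell and fibroblast markers, 6 were higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 1.80 (camera adjusted p = 3.5e-06; adjusted p = 0.0823 with an estimated correlation) and 1.21 with a common floor (adjusted p = 5.1e-05). In the slide-blocked fit 2 were higher, at a median of 2.95 (camera adjusted p = 2.2e-07, and 0.0659 in that fit with an estimated correlation). Pdgfrb, the platelet-derived growth factor receptor of stellate cells, was at least 4.84-fold higher (adjusted p = 2.6e-05), and Lrat, which stores retinol as esters, at least 6.37-fold (adjusted p = 0.00025). Of 15 Kupffer cell markers 2 were higher and 0 lower, Itgam (2.78 ± 0.56, adjusted p = 0.011, above background on 1 male vehicle array) and Csf1r (1.85 ± 0.37, adjusted p = 0.0098). The Kupffer list median was 0.64 (camera adjusted p = 0.00253; adjusted p = 0.682 with an estimated correlation and 0.197 with slide as a block). Of 12 endothelial markers 2 were higher and 1 lower, with a median of 0.37 (camera adjusted p = 0.425), and 1.74 with slide as a block (adjusted p = 0.000379, and 0.475 in that fit with an estimated correlation). Of 11 cholangiocyte markers 2 were higher and 1 lower, with a median of 0.20 (camera adjusted p = 0.0298, and 0.504 with an estimated correlation). With slide as a block it was 2.23 (adjusted p = 0.00372, and 0.35 in that fit with an estimated correlation). Lymphocyte markers did not pass (median 0.84, 0 of 10 past the threshold, camera adjusted p = 0.133), nor did erythrocyte markers (median -0.61, 1 of 5 lower, camera adjusted p = 0.585).

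Cell cycle genes had a median of 0.55, with 5 of 28 higher and 1 lower, Myc (10 and 1 adjusted over the list alone; camera adjusted p = 4.0e-05; adjusted p = 0.449 with an estimated correlation; 0.00133 with slide as a block). The replication helicase gene Mcm5 was higher by 1.52 ± 0.30 (adjusted p = 0.01) and the mitotic kinase Aurkb by 1.45 ± 0.28 (adjusted p = 0.0091), each above background on 1 male vehicle array. Fatty acid oxidation genes had a median of -0.57, with 6 of 25 lower and 1 higher (12 and 1 adjusted over the list alone; camera adjusted p = 0.00719; adjusted p = 0.538 with an estimated correlation; 0.00774 with slide as a block). Endoplasmic reticulum stress genes had a median of -0.54, with 3 of 18 lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.00422; adjusted p = 0.666 with an estimated correlation; 0.00372 with slide as a block). Examples were the fatty acid hydroxylase Cyp4a1 (-1.76 ± 0.38, adjusted p = 0.014) and the pseudokinase Trib3 (-0.90 ± 0.21, adjusted p = 0.018). The cell cycle, fatty acid oxidation and endoplasmic reticulum stress lists did not pass with slide as a block and an estimated correlation (camera adjusted p 0.475 to 0.476). Inflammation genes passed narrowly, with 5 of 37 higher and 1 lower (median 0.35, camera adjusted p = 0.0499; adjusted p = 0.682 with an estimated correlation), and had a median of -0.13 with slide as a block (adjusted p = 0.247). Besides endothelial markers, the lists that passed between the sexes in vehicle with slide as a block and not without it were bile acid genes (median -0.93, adjusted p = 0.0021), hepatocyte identity (-0.61, 0.00609), xenobiotic metabolism (-1.06, 0.00877) and extracellular matrix genes (0.57, 0.0249, against -0.10 without the block). With an estimated correlation in that fit the adjusted p of these lists, endothelial markers included, were 0.475 to 0.477. The alarmin Il33 was higher by 3.32 ± 0.43 (adjusted p = 0.0016) and Cx3cl1 lower by -2.97 ± 0.48 (adjusted p = 0.0042).

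In the limma fit 3655 genes differed between the sexes in vehicle, 1547 higher and 2108 lower in females (7948 at an unadjusted p under 0.05). The groups did not overlap for 31.2% of genes, against 10% for exchangeable arrays, which these groups on separate slides are not. Of the called genes, 990 were above background on none of the 3 male vehicle arrays: 574 higher calls, and lower calls whose male level was not measured. Of these lower calls, 97 were above background on no array of either group. The share of higher calls was 42.3%, and 62.8% with quantile normalization (2908 and 1726), while the median difference of all genes was -0.06 and 0.09 in these settings. Fits to only the 2 groups compared called 793 genes in vehicle and 1006 in dexamethasone. No slide held both groups. With slide as a block, where the standard error was 1.87 times as large, 131 genes passed (46 higher and 85 lower), 91 of them called the same way without it. In this fit to the same arrays 3643 of the 3655 kept their sign. Obp3, Mup4 and Pdgfrb passed in that fit (adjusted p 0.0006 to 0.022) and Lrat did not (adjusted p = 0.057); no blocked size is given for them, since 1 group is below background. The blocked differences were 5.81 for Cyp2c7 (adjusted p = 0.075), 2.37 for Cyp2c12 (adjusted p = 0.26), -2.29 for Cyp2c11 (adjusted p = 0.43) and -6.88 for Cyp3a2 (adjusted p = 0.22). Of 77 named genes that passed, 40 kept their call whichever array was left out. Cyp2c11 lost it without male vehicle replicate 1 or 3, female vehicle replicate 1 or 2, male dexamethasone replicate 1 or female dexamethasone replicate 2 (adjusted p up to 0.148). Cyp3a2 lost it without male vehicle replicate 2 or 3 or female vehicle replicate 1 or 3 (up to 0.103), Fkbp5 without male vehicle replicate 1 or 2 or any 1 of the 6 female arrays (up to 0.12) and Trib3 without female vehicle replicate 1 (0.0733). The count was 1657, 2014 and 1917 without female vehicle replicates 1, 2 and 3.

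Under dexamethasone the sexes still differed in the same families. Obp3 was at least 1360-fold lower in females (adjusted p = 4.2e-08, n = 3 per group) and Mup4 at least 1204-fold lower (adjusted p = 4.3e-07). Akr1b7 was at least 37.4-fold higher (adjusted p = 0.00044) and the plasma glycoprotein gene A1bg at least 10.7-fold higher (adjusted p = 0.0011). Cyp2c7 was higher by 4.20 ± 0.59 (adjusted p = 0.0062), Sult2a2 by 4.94 ± 0.78 (adjusted p = 0.0098) and Cyp2c12 by 2.36 ± 0.44 (adjusted p = 0.02). Cyp3a2 was lower by -5.48 ± 1.22 (adjusted p = 0.041), above background on 2 of 3 female arrays, and Cyp2c11 did not pass (-1.77 ± 0.67, adjusted p = 0.19). Fkbp5 (-0.75 ± 0.18, adjusted p = 0.059) and Tat (0.00 ± 0.21) did not pass.

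Of 20 female-biased genes, 11 were higher and 1 lower, again Slc22a8 (-4.31 ± 0.50, adjusted p = 0.0024), with 12 and 2 adjusted over the list alone. The median was 1.29 (camera adjusted p = 2.7e-09; adjusted p = 0.0226 with an estimated correlation) and 1.41 with slide as a block (adjusted p = 1.6e-06). Of 16 male-biased genes, 5 were lower and 1 higher, Lifr, the receptor of leukemia inhibitory factor (1.61 ± 0.35, adjusted p = 0.036); adjusted over the list alone 9 were lower and 1 higher. Their median was -1.30 (camera adjusted p = 8.2e-06; adjusted p = 0.177 with an estimated correlation), and -1.07 with slide as a block (adjusted p = 0.000109). Of 12 stellate-cell and fibroblast markers 2 were higher and 0 lower (5 and 0 adjusted over the list alone), Pdgfrb (3.15 ± 0.28, adjusted p = 0.00035) and Lrat (2.90 ± 0.39, adjusted p = 0.0055). Their median was 0.91 (camera adjusted p = 4.9e-05, and 0.17 with an estimated correlation). With slide as a block it was 1.81 (adjusted p = 1.6e-06, and 0.100 in that fit with an estimated correlation). Kupffer cell markers had a median of 0.77 with 0 of 15 past the threshold (camera adjusted p = 0.00114; adjusted p = 0.624 with an estimated correlation and 0.199 with slide as a block). Endothelial markers had a median of 0.81 with 1 of 12 higher (camera adjusted p = 0.0259; adjusted p = 0.624 with an estimated correlation) and an adjusted p of 5.5e-05 with slide as a block (0.406 in that fit with an estimated correlation). Cholangiocyte markers had a median of -0.05 with 0 of 11 past the threshold (camera adjusted p = 0.759), and hepatocyte identity one of -0.18 (camera adjusted p = 0.19).

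The cell cycle list passed with a median above 0 (0.60, camera adjusted p = 4.9e-05), with 2 of 28 genes higher and 1 lower in females. The lists of fatty acid oxidation (-0.44, 5.2e-05, 1 of 25 lower), endoplasmic reticulum stress (-0.47, 8.3e-05, 1 of 18 lower) and bile acid genes (-0.17, 0.0259, 2 of 20 lower) passed with medians below 0. With an estimated correlation none of these 4 lists passed (adjusted p = 0.383, 0.258, 0.431 and 0.624). Interferon-response genes passed with slide as a block (median 0.51, adjusted p = 0.0108; 0.465 in that fit with an estimated correlation) and not without it (0.147). In the limma fit 769 genes passed, 313 higher and 456 lower in females (4858 at an unadjusted p under 0.05). The groups did not overlap for 32.3% of genes, against 10% for exchangeable arrays, which these groups on separate slides are not. With slide as a block 21 passed, 8 higher and 13 lower, 18 of them called the same way without it. In this fit to the same arrays all 769 kept their sign. Obp3 (adjusted p = 0.00051) and Mup4 (0.0024) passed in that fit and Akr1b7 (0.077) did not. The blocked differences were 3.67 for Pdgfrb (adjusted p = 0.056) and 2.09 for Cyp2c12 (0.49). Without the 4 arrays of slide 1, 1541 genes passed. Of 37 named genes that passed, 13 kept their call whichever array was left out. Cyp2c12 lost it without male dexamethasone replicate 1 or 2 or any female dexamethasone array (adjusted p up to 0.0924), Sult2a2 without female dexamethasone replicate 2 (0.053), and Cyp3a2 without male vehicle replicate 2, female vehicle replicate 3 or any 1 of the 6 dexamethasone arrays (up to 0.125). Lifr lost it without female vehicle replicate 1 or 3, male dexamethasone replicate 1 or 3 or any female dexamethasone array (up to 0.139). The count was 443, 422 and 323 without male dexamethasone replicates 1, 2 and 3, 357, 156 and 258 without female dexamethasone replicates 1, 2 and 3, and 1117 without male vehicle replicate 3.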

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

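The splits of arrays and the 100 regroupings, the tests of response size and of narrowing, and the median of the second stellate list were planned before their values were seen; the other tests weighed here were chosen after the result they address was seen. For slide offsets, response size, hepatocyte share, the second stellate list and the regroupings of the interaction, the rule for reading the value was also changed after a first result.

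The dexamethasone response differed between the sexes, by the limma interaction test, for 28 genes, and a named gene is listed here for that difference. The female minus male differences were 3.83 for Adamtsl2, 3.45 for Klk1b3, 2.98 for Myzap, 2.91 for Cdh23, 2.56 for Rtl3, 2.503 for Kl, 2.13 for Reg3a, 1.92 for Zfp474 and -1.57 for Vrk2, with adjusted p from 0.027 to 0.049. The kept probes of Vrk2 disagreed in sign. Adamtsl2, Cdh23, Klk1b3, Rtl3, Kl and Myzap were above background on 0 male vehicle arrays, so the differences given for them are calculated from dim signals and are not measured sizes. With slide as a block their adjusted p were 0.058 to 0.222 and with replicate pairs as blocks 0.0946 to 0.108. In simulated data each of these fits recovered 0% of interaction genes with a log2 change of 2. The simulation held no slide effect, no shared deviation of replicate pairs and no larger change, so it cannot say what this loss means. Over the 28 genes the slide-blocked differences were a median 1.012 of the unblocked ones, in a fit to the same arrays. Each named gene lost its call without female vehicle replicate 1 or 3 or any female dexamethasone array, with an adjusted p of up to 0.158 over the arrays left out. Of 100 regroupings of the sexes within each treatment, drawn from 200, 2 gave as many calls, the real one included. The other one gave 4465 calls: its vehicle arrays were of 1 sex and its dexamethasone arrays of 1 sex, with the sexes swapped in 1 treatment alone. Its contrast is then, up to sign, the sum of the sex differences in vehicle and dexamethasone and not an interaction. The highest of the regroupings besides it gave 3. These regroupings break the replicate pairs, so the bound written beforehand, fewer than 5 of 100, was wrong for this design. Of the 10 regroupings that keep the pairs 1 gave as many, the real one, and the highest other gave 0, but with 10 no share under 0.05 can be reached.

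By the same interaction, stellate-cell and fibroblast markers had a median of -0.99 and cholangiocyte markers of -0.43 (camera adjusted p = 0.0295 each; 0.762 each with an estimated correlation). With slide as a block the adjusted p were 0.157 and 0.0136, and with replicate pairs as blocks 0.0113 each. With both blocks they were 0.54 and 0.461, and fry gave 0.714 each. No list passed without male vehicle replicate 2 or 3, female vehicle replicate 2, male dexamethasone replicate 1 or female dexamethasone replicate 1, and 1 passed without female vehicle replicate 1 or 3 or female dexamethasone replicate 2. On all male vehicle arrays 6 of the 12 stellate and 4 of the 11 cholangiocyte markers were above background, so both medians rest in part on dim signals.

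More genes passed in the male than in the female response, 2676 against 1098, in the fit that shares the spread between groups, an order that turned in fits to only the 2 groups compared (244 against 2675) and with array weights (864 against 4918). Among genes above background on all 12 arrays the male count was 3.94 times the female (2078 and 528), which argues against signals near background as the whole cause. It cannot decide on the quality of slide 1, since this fit too shares the spread between groups. Among these genes the median SD between arrays was 0.305 in male vehicle and 0.147 in female vehicle. Larger male responses stay open: the median male to female ratio was 0.853 among 467 genes called in females. The bound written beforehand would count this against them, but choosing genes by the female call raises the female response, and among 1466 genes called in males the female to male ratio was 0.479, so selection sets both. The crossing of slides stays open, since the male count was 1.57 times the female with slide as a block, between the bounds set, and a difference between the sexes is untested beyond the 28 interaction calls.

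More genes differed between the sexes in vehicle than in dexamethasone, 3655 against 769, in the fit that shares the spread. This order too turned in fits to only the 2 groups compared (793 against 1006) and with array weights (2048 against 3715). The vehicle count was 4.88 times that in dexamethasone among genes above background on all 12 arrays (2878 and 590), which argues against signals near background as the whole cause. It cannot decide on the quality of slide 1, since this fit too shares the spread between groups. An offset of whole slides stays open: the blocked difference was a median 1.006 of the unblocked one (0.989 to 1.02 in a bootstrap over genes). That interval does not measure the spread between arrays, and slide 1 is tied to the other slides by 1 array, male dexamethasone replicate 1. A narrowing by dexamethasone stays open too, with a median vehicle to dexamethasone ratio of 1.03 (0.974 to 1.07, again over genes) among 387 genes chosen by their call in dexamethasone, and 0.486 for the mirrored ratio.

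Stellate-cell and fibroblast markers had a higher median in female cultures, 1.80 in vehicle (1.21 with a common floor) and 0.91 in dexamethasone. Past the threshold were 6 of 12 in vehicle and 2 of 12 in dexamethasone. With an estimated correlation the list passed camera in neither (adjusted p = 0.0823 and 0.17). The vehicle difference cannot be had without slide 1, which holds all male vehicle arrays. The background of slide 1 is argued against as the whole cause by dexamethasone cultures off that slide (male replicates 2 and 3), with a median of 1.09 (0.806 to 1.66 in a bootstrap over markers, 11 of 12 markers positive), against 0.91 with all dexamethasone arrays. That interval does not measure the spread between arrays. More stellate cells or fibroblasts in the female cultures stay open, as a hypothesis: a second list of 29 measured genes had a median of 0.30 (99.8th percentile of 10000 random lists, with 8 higher and 0 lower). Of the 8 higher genes only Mgp was above background on all male vehicle arrays. Most of the 12 members measured on all of these arrays had a negative difference, so the positive median rests on dim male signals. With a common floor, which turns changes from dim levels into lower bounds, 12 of the 29 genes were positive and 8 negative, with a median of 0 and a mean of 0.39, against a 95th percentile of 0.125 for the mean of random lists.

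A lower hepatocyte share, which would raise all other cell types alike, stays open too, since stellate markers parted from the other types in some comparisons and not in others. In vehicle they exceeded endothelial markers by 1.54 (permutation p = 0.00819), Kupffer markers by 0.92 (permutation p = 0.0449), cholangiocyte markers by 1.26 (permutation p = 0.0384) and the 38 markers of these types together by 1.21 (permutation p = 0.00219). In dexamethasone the excess was 0.33 (permutation p = 0.384), 0.29 (0.337), 1.17 (0.00206) and 0.56 (0.041), in this order. Dim signals limit this: 6 of 12 stellate, 3 of 12 endothelial, 14 of 15 Kupffer and 4 of 11 cholangiocyte markers were above background on all male vehicle arrays. With the common floor the excess over the types together was 0.63 in vehicle (permutation p = 0.0227) and 0.16 in dexamethasone (0.397), that over endothelial markers 0.98 (0.00445) and 0.31 (0.144), that over Kupffer markers 0.27 (0.357) and -0.23 (0.239), and that over cholangiocyte markers 0.74 (0.0875) and 0.52 (0.0326). Under a slide block and no floor, stellate markers exceeded Kupffer markers by 2.06 in vehicle (permutation p = 0.00073) and 1.28 in dexamethasone (0.0014), cholangiocyte markers by 1.14 (0.143) and 1.63 (0.00141), and endothelial markers by 0.84 (0.253) and 0.09 (0.875). Over the types together the blocked excess was 1.41 (permutation p = 0.0128) and 1.007 (0.0153), and with the floor as well 1.29 (0.00123) and 0.78 (0.00501).

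Lists as wholes also went both ways on a lower share. In vehicle, hepatocyte identity had a median of -0.36 (0 higher, 2 lower, camera adjusted p = 0.0753). Its camera adjusted p was 0.00609 with slide, 0.0337 with the replicate number alone and 0.031 with both as blocks. Kupffer markers had a median of 0.64 (camera adjusted p = 0.00253, and 0.197 with slide as a block). With an estimated correlation the adjusted p were 0.735 and 0.682. Endothelial markers did not pass in vehicle (0.37, camera adjusted p = 0.425), but did there with slide as a block (1.74, 0.000379) and in dexamethasone (0.81, 0.0259). With an estimated correlation neither of these calls was kept (0.475 in the blocked fit and 0.624). In dexamethasone neither cholangiocyte markers (-0.05, 0 of 11 past the threshold, 0.759) nor hepatocyte identity (-0.18, 0.19) passed. All these comparisons take genes as units.

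Among the markers, Tagln had the probe with the highest signal, which does not rank transcripts by abundance, since probes differ. It was at 6.20 in male and 7.08 in female vehicle cultures (difference 0.87, adjusted p = 0.37), and Col1a1 at 0.25 and 1.45 (adjusted p = 0.28). The 5 members of the second list with the highest signal in female vehicle cultures were Vcl (-0.41, adjusted p = 0.206), Mgp (2.95, 0.00704), Nes (-0.95, 0.411), Lox (-0.03, 0.987) and Sparc (2.15, 0.0775), all above background on all male vehicle arrays. Of the 12 markers 6, and of the 29 genes 12, were above background on all male vehicle arrays, and 0 of either list are in another list. A sex difference of the animals or their cells was not tested apart from the isolation of each culture.

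The counts were also set against other splits of the same 6 arrays. For the male response, the female response, the sexes in vehicle and the sexes in dexamethasone, 1 of 10 splits gave as many calls, the real one (2676, 1098, 3655 and 769). The highest other splits gave 1, 0, 2 and 0. With 10 splits no share under 0.05 can be reached. Among the 3 other splits that part all replicate pairs the highest were 1 in males and 0 in females.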

How the results depend on the processing

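The slide and replicate blocks together, the common floor, the genes above background on the arrays compared and the fit without slide 1 were chosen after the data were seen. Counts below are of genes past the threshold in limma unless said otherwise, and the cause of each move was not tested except where the setting itself removes arrays, genes or calls. In this order, the unaltered counts were 2676 for the male response, 1098 for the female, 28 for the interaction, 3655 for the sexes in vehicle and 769 in dexamethasone, with 529 shared and 3, 13, 2, 9 and 9 gene lists.

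The authors' value table, the mean of a gene's probes and the probes tested singly kept all counts within 1.5 times.

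Normexp with quantile normalization gave 693 in females, 0 for the interaction (3020 at an unadjusted p under 0.05) and 6 lists in males. It reversed Akr1b10 (0.00469), Cyp1b1 (0.0913) and Hgf (0.0887) in males and Ppargc1a (0.0321) between the sexes in vehicle, all below background in both groups. Quantile normalization alone gave 561 in females, 293 for the interaction and 1 interaction list, and reversed the interaction of Kl (-0.18). The array median gave 4 for the interaction. Quantile normalization, with or without normexp, turned the median of no called list. Lists were not run with the array median, whose shift of all genes in females (a median of -0.09 against -0.02) is larger than the 0.06 of the insulin and growth hormone list. Quantile normalization ended the vehicle calls of the cholangiocyte (adjusted p = 0.11), inflammation (0.156) and Kupffer (0.0585) lists and the interaction call of the cholangiocyte list (0.497); normexp ended the vehicle calls of the inflammation (0.092) and fatty acid oxidation (0.058) lists.

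Without a filter on dim probes the counts were 11120 (1854 higher, 9266 lower), 723 (548, 175), 6681 (6290, 391), 12526 (2078, 10448) and 485 (182, 303). Higher calls were then 16.7% in males, 94.1% for the interaction and 16.6% in vehicle, against 51.6%, 71.4% and 42.3% with the filter. With probes above background on all 12 arrays they were 531 in females and 7 for the interaction, and 7 for the interaction with genes above background on the arrays compared. A common floor gave 52 for the interaction, 5 lists in males and 1 for the interaction.

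Slide as a fixed block gave 471, 300, 2, 131 and 21, with 90 shared, 8 lists in females and 1 for the interaction. As a random block it gave 441 for the interaction, 5996 in vehicle and 1745 in dexamethasone, at a correlation of -0.110 within slides. Within slide 1 the male response had 0 (2105 at an unadjusted p under 0.05). Without slide 1 the female response had 2417 and the sexes in dexamethasone 1541.

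Replicate pairs as blocks gave 4175, 1793, 0 for the interaction (4382 at an unadjusted p under 0.05) and 1484 in dexamethasone, with 1015 shared. Between the sexes this block pairs arrays by number alone. Besides calls given with the report, it gained Itgam and Ptprc in males and Rsad2 in females, and lost Cldn4 in females and Ramp2 between the sexes in dexamethasone. Between the sexes it gained Cd3g, Nr1d2 and Pck1 (adjusted p = 0.0192) in vehicle, and Atf3, Csf1r, Fkbp5 (0.0244), Gzmb and Vim in dexamethasone. It also gained the bile acid (0.0312), hepatocyte identity (0.0337), lymphocyte (0.0312) and xenobiotic (0.0312) lists in vehicle, and the heat shock (0.0422) and lymphocyte (0.0294) lists in dexamethasone. With an estimated correlation in that fit their adjusted p were 0.282, 0.614, 0.293 and 0.282 in vehicle and 0.462 and 0.303 in dexamethasone. It changed no other call of a named gene or list. With both blocks limma called 0 in males, 0 in females and 0 for the interaction (6990, 3293 and 3713 at an unadjusted p under 0.05), 14 in vehicle, 9 in dexamethasone and 0 interaction lists.

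Fits to only the 2 groups compared gave 244, 2675 and, in vehicle, 793 against 1006 in dexamethasone. Trend and robust options gave 7 for the interaction. Array weights gave 864, 4918, 110, 2048 and 3715, counts that depend on the order of genes and are unstable. An adjusted p under 0.01 left 659, 246, 0 for the interaction (3208 at an unadjusted p under 0.05), 1085 and 156, and a 2-fold minimum left 1426 in males and 1922 in vehicle. An estimated correlation left 1, 1, 0, 0 and 1 lists by camera; fry left 7 in females, 0 for the interaction and 5 in dexamethasone.

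Leaving out each array in turn gave 1173 to 3540 in males, 310 to 1462 in females, 0 to 579 for the interaction, 1657 to 4430 in vehicle and 156 to 1117 in dexamethasone, with 210 to 602 shared. The lists ran from 3 to 5, 6 to 16, 0 to 3, 5 to 13 and 8 to 10. The extremes came without male dexamethasone replicate 2 (1173), female dexamethasone replicate 2 (310, 156 and 210), female vehicle replicate 1 (1657), male vehicle replicate 1 (602) and male vehicle replicate 3 (3540, 1462, 579, 4430 and 1117). Of the named genes called, 40 of 64, 30 of 49, 0 of 9, 40 of 77 and 13 of 37 kept their call in every such fit.

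Signal over background limits the male vehicle group most: 887 calls in the male response and 990 in vehicle were above background on no male vehicle array. Of these, 549 and 574 were rises, and the others were falls or lower calls whose male vehicle level was not measured.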
